A study of Mus musculus with 18 samples.

How the data were processed

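RNA was sequenced from sorted CD11c-high dendritic cells in 18 libraries, 3 in each of 6 groups. Groups and replicate numbers were taken from the sample titles. The labels mention 5 biological replicates in the treatment protocol and triplicates elsewhere, and 3 libraries per group were analysed here. The labels do not say whether the libraries of a group came from separate animals or cultures. The p-values therefore measure the spread among these samples.

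The values in the files are gene-level expected counts and TPM, per the file headers. They were deposited by the authors as RSEM output on the mm10 assembly, after base calling with bcl2fastq, per the submitters' processing notes. The notes give no versions. The design text in the labels also names other aligners and tests, whose output was not used here. TPM values were deposited scaled over all genes of a library and were used only as an alternative scale. Strandedness was not given in the sources used here, so overlapping and antisense genes cannot be separated. Genes with near-identical copies are uncertain.

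Each library listed 23420 genes. Total expected counts per library ranged from 8056831 to 12068759. Intervals on low counts cover counting error only. Pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom from 3.64 to 36.3 over genes with at least 20 counts in the pair.

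Expected counts were rounded to whole numbers. The filterByExpr function, given the groups, kept 11876 genes, and library sizes were scaled with TMM. All 6 groups were fitted together with edgeR 4.0.16 under R 4.3.3, without covariates, using the robust quasi-likelihood fit and F-test. The common biological coefficient of variation was 0.13. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were called. There were 7 comparisons between groups and 2 interactions. CPM values use TMM-scaled library sizes. Log2 fold changes are given with their standard errors.

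The gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Part 1 of the rule took Bag6. Part 2 took the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between the libraries compared, leaving out unnamed gene models. For interactions it took 4 in each direction, without the condition on overlap. Part 3 took, for each list discussed, the 3 called members with the smallest p, or the 3 members with the smallest p where none was called. Part 4 took 20 readout genes whatever their result. The rule also took 1 gene that is not reported here. The 30 lists hold pathway genes, cell-type markers, genes flanking Bag6 and sex-linked genes. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and adjusted over the 30 lists. Camera with an estimated correlation and fry were alternatives.

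Alternatives for genes were RLE and upper-quartile scaling, DESeq2 1.42.0, no count filter, and a filter of at least 5 CPM in 3 libraries. Others were a fit of only the groups compared, the replicate number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1), a 2-fold requirement, and each library left out in turn. Removal of Rn45s, and of the first replicate of both cKO groups, was chosen after seeing the data. The TPM scale means log2(TPM + 1) unless said otherwise. On it the median of all genes was -0.25 for the genotype interaction, -0.19 for LPS in WT cells, -0.12 for the cytokines alone and -0.11 for LPS added to the cytokines.

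Whether replicate numbers pair libraries was checked with the correlation of same-numbered libraries' deviations from their group means, over 8116 genes. Of 15 pairs of groups, 2 had every correlation over 0.1. Of the groups compared, these were WT medium and WT cytokines (0.35, 0.21 and 0.45), where the pairing comes from the data and not from the labels.

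Similarity of 2 comparisons was measured with Pearson's r, Spearman's rho and the covariance of log2 fold changes across genes, which are not independent replicates. Chance values came from 20 simulations of unchanged groups with the same shared controls, and errors from a jackknife over left-out libraries. Other splits of the libraries were all 10 for each pair of groups and 60 for each interaction.

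The procedure was tested on simulated counts for cKO against WT under LPS, over 11750 genes. It recovered 34.3% of 67 genes changed 1.5-fold, 76.9% of 65 changed 2-fold and 89.4% of 66 changed 4-fold. The bound for accepting the last share was lowered to 80% after it was seen. The 7 genes missed at 4-fold had a median mean count of 4.33, against 276 for the 59 recovered. Of 159 calls, 7 were of unchanged genes. cKO against WT in medium, simulated unchanged, gave 0 calls. The median log2 error at 4-fold was -0.014. Camera called only the shifted list, which an estimated correlation also called. Change in more genes was not simulated.

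Gene positions came from a RefSeq table of the GRCm38 assembly, which matched 11837 of the tested genes (99.67%). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.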

Results

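Gene expression was measured by RNA sequencing in bone-marrow-derived dendritic cells of C57BL/6 mice, which are antigen-presenting cells grown from marrow progenitors in GM-CSF. Live cells with high CD11c, a surface integrin of dendritic cells, were sorted after 8 hours of treatment. The 18 libraries fell into 6 groups of 3. Wild-type (WT) cells were kept in medium, given lipopolysaccharide (LPS, a bacterial cell wall component sensed by TLR4), given interleukin-10 with TGF-beta (both immunosuppressive cytokines), or given LPS together with both cytokines. Cells carrying floxed Bat3 alleles and a CD11c-driven Cre recombinase (cKO) were kept in medium or given LPS. Bat3 is the older name of Bag6, a chaperone that guides tail-anchored proteins and misfolded polypeptides. Of 23420 genes, 11876 had enough counts to be tested.

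Bag6 lies on chromosome 17 at positions 35135156 to 35147321 of the mouse mm10 (GRCm38) assembly. Its level was 23.5 ± 0.982 CPM (counts scaled to library size; SD, n = 3) in WT medium and 24.0 ± 0.757 in WT LPS. It was 26.1 ± 0.258 with the cytokines and 26.5 ± 1.82 with LPS and cytokines. In cKO cells it was 5.56 ± 1.52 in medium and 9.36 ± 2.68 in LPS, and each of the 6 cKO libraries lay below each of the 12 WT libraries. The log2 fold change between cKO and WT was -2.08 ± 0.17 (SE) in medium (adjusted p = 9.1e-08) and -1.36 ± 0.17 in LPS (adjusted p = 9.3e-06). Bag6 did not differ between treatments of WT cells at this depth, with log2 fold changes from 0.02 to 0.15 and adjusted p of 0.48 or higher. The counts cover the whole gene and do not separate the deleted exons from the rest.

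**Figure D1:**
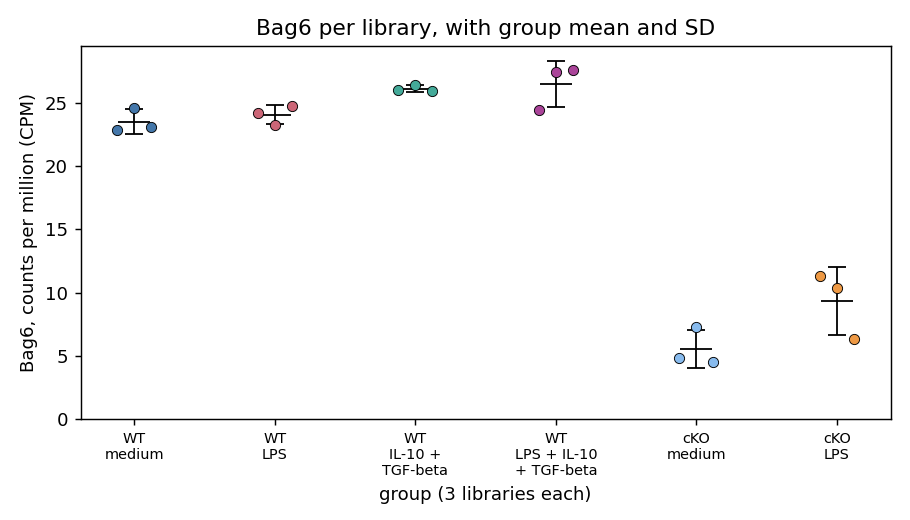
Bag6 in each library, in CPM on a linear axis from 0, by group. Points are libraries, and the line and bars give the group mean and SD of 3 libraries. The cKO libraries lie between 4.56 and 11.3 CPM and the WT libraries between 22.8 and 27.6 CPM.

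The first principal component of log2 CPM held 48.8% of the variance and separated cultures with and without LPS. The second held 24.4% and separated WT cultures with cytokines from all others. Ribosomal precursor RNA (Rn45s) made up 2.43% ± 1.41 of counts in cKO medium and 7.41% ± 0.895 in WT medium (SD). Means of groups other than cKO medium were 5.85% to 7.56%. The first replicate of each cKO group had the female pattern of sex-linked genes, with Xist at 526 and 1010 CPM, while the other 16 libraries had the male pattern.

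**Figure D2:**
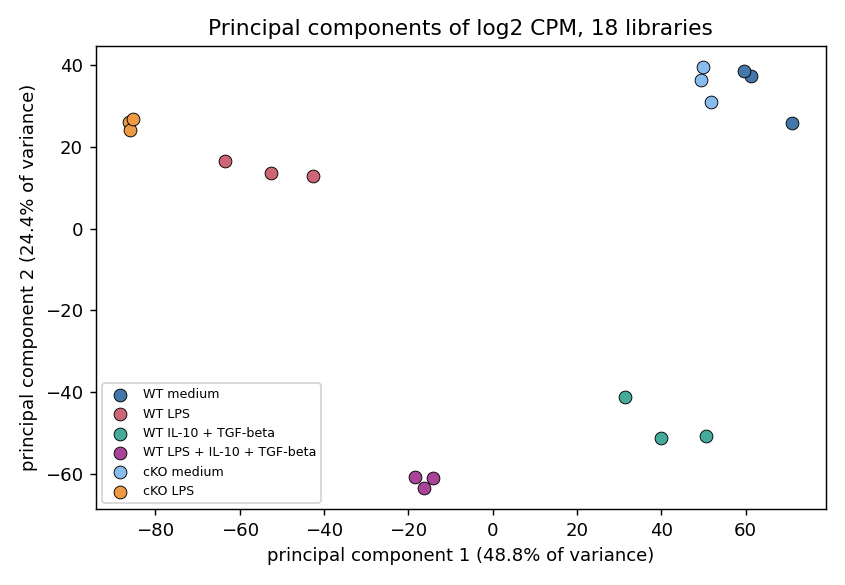
Principal components 1 and 2 of log2 CPM over the tested genes, with the percentage of variance on each axis. Points are the 18 libraries, coloured by group. The 3 cKO LPS libraries lie at the LPS end of the first axis, between -86.3 and -85.4, beyond the WT LPS libraries (-63.4 to -42.6).

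The effect of Bag6 deletion in resting cells was read from cKO and WT cells in medium. Pim1, a serine/threonine kinase induced by STAT signalling, rose from 11.8 ± 0.813 to 223 ± 7.53 CPM (SD, n = 3), a 18.9-fold difference. Cebpb, a transcription factor of myeloid and inflammatory gene expression, was 34.6-fold higher, Snx20, a sorting nexin, 20.1-fold, and the zinc finger gene Zfp622 9.71-fold. Dusp5, a phosphatase of ERK kinases, and Ptx3, a soluble pattern recognition molecule, were 9.43-fold and 8.95-fold higher. The largest falls besides Bag6 were in Emr4, an adhesion receptor of myeloid cells (log2 fold change -3.84 ± 0.61), H2-T9, a non-classical MHC class I gene (-2.73 ± 0.57), the focal adhesion gene Tns1 (-2.48 ± 0.31), the adaptor Blnk (-2.20 ± 0.55) and the corepressor Hr (-2.11 ± 0.36). H2-T9 shares reads with near-identical family members and its value is uncertain. Adjusted p for these genes ranged from 1.5e-15 for Pim1 to 0.0094 for Blnk. H2-T9 lost its call when the fit held only the groups compared (adjusted p = 0.12), and Blnk without the first replicate of both cKO groups (-2.12, adjusted p = 0.051).

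Pim1 lies on chromosome 17 at 29490785 to 29496111, Cebpb on chromosome 2 at 167688915 to 167690432, Snx20 on chromosome 8 at 88626561 to 88636133 and Zfp622 on chromosome 15 at 25984366 to 25998482. Of the fixed readout genes, 6 rose and 0 fell. Il6 and Il1b, both inflammatory cytokines, rose by log2 1.48 ± 0.20 (adjusted p = 2.7e-05) and 1.31 ± 0.17 (adjusted p = 1.5e-05). Socs3, a feedback inhibitor of cytokine signalling, rose by 0.99 ± 0.15, Xbp1, a regulator of the endoplasmic reticulum stress response, by 0.49 ± 0.09 and Tsc22d3, a glucocorticoid-induced gene, by 1.10 ± 0.20. Cyp11a1, the first enzyme of steroid hormone synthesis, rose by 1.92 ± 0.53 (adjusted p = 0.011), and this call was lost without cKO medium replicate 1 (1.49, adjusted p = 0.07), WT medium replicate 3 (1.55, adjusted p = 0.055) or the first replicate of both cKO groups (1.49, adjusted p = 0.06). The remaining 14 readouts did not pass, among them Tnf (0.03 ± 0.16), Cd86 (-0.16 ± 0.43), Cd40 (-0.33 ± 0.83), Havcr2, the gene of the checkpoint receptor TIM-3 (-0.14 ± 0.46), Il10 (0.76 ± 0.99) and Il12b (0.84 ± 2.05). Ddit3 (0.68 ± 0.27) passed without WT medium replicate 2 (0.97, adjusted p = 0.016), with DESeq2 (0.66, adjusted p = 0.031) and with the replicate block (0.69, adjusted p = 0.031), as did Cd274 (0.38 ± 0.20) with the block (0.38, adjusted p = 0.043). The Il10 estimate rested on 5 and 8 counts per group.

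Cytokine, stress and glucocorticoid response genes were among those higher in cKO medium. Of 28 tested proinflammatory cytokines and chemokines, 10 rose and 1 fell (10 and 2 adjusted over the list alone), with Ccl3 at 1.14 ± 0.11 and Ccl4 at 1.27 ± 0.13, both chemokines for monocytes and T cells (camera adjusted p = 0.0014, and 0.67 with an estimated correlation). Of 18 glucocorticoid receptor targets, 12 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 4.2e-05, and 0.21 with an estimated correlation). Its members included the MAP kinase phosphatase Dusp1 (2.19 ± 0.16), the mRNA-destabilising factor Zfp36 (1.44 ± 0.14) and the kinase Sgk1, which fell (-1.43 ± 0.16). Of 31 PERK and ATF4 stress genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone), led by Ddit4, an inhibitor of mTORC1 (2.79 ± 0.25), Gadd45a (2.15 ± 0.24) and Ppp1r15a (1.22 ± 0.15), with adjusted p = 0.023 and adjusted p = 0.65 with an estimated correlation. The list median was 0.08, and -0.01 on the TPM scale. Of 24 p53 targets, 11 rose and 1 fell (11 and 1 adjusted over the list alone), among them Btg2 (1.41 ± 0.12) and the cell cycle inhibitor Cdkn1a (1.03 ± 0.12), with adjusted p = 0.02 and adjusted p = 0.50 with an estimated correlation. Without WT medium replicate 2 the PERK and ATF4 list and p53 targets lost their calls (adjusted p = 0.064 each). The former also did without cKO medium replicate 2 (adjusted p = 0.055). Of 16 immediate early genes, a list written after the values were seen, 12 rose and 0 fell. Lists can share members, so these rises are not independent.

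Of 20 NF-kB pathway genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.011, and 0.67 with an estimated correlation), with Nfkbiz at 1.62 ± 0.16 and the inhibitor Tnfaip3 at 0.97 ± 0.13. Of 33 type I interferon-stimulated genes, 7 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 0.0043, and 0.80 with an estimated correlation), among them Irgm1, an interferon-inducible GTPase (-1.46 ± 0.27), and Trim30a (-0.67 ± 0.10). Of 33 genes of the TCA cycle and oxidative phosphorylation, 13 fell and 0 rose (14 and 0 adjusted over the list alone; adjusted p = 0.0025, and 0.67 with an estimated correlation), with Fh1 at -0.61 ± 0.11. Among IL-10 and STAT3 targets 5 rose and 4 fell of 20 (6 and 6 adjusted over the list alone; adjusted p = 0.025, and 0.67 with an estimated correlation), and Pim1 is a member. Of 26 tolerogenic molecules 9 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.041, and 0.67 with an estimated correlation), with the arginase gene Arg2 at 1.56 ± 0.18 and the receptor kinase Axl at -0.89 ± 0.11. Without cKO medium replicate 2 the number of lists called fell from 10 to 5. The NF-kB, TCA cycle, STAT3 and tolerogenic lists (adjusted p of 0.051, 0.058, 0.06 and 0.078) and the PERK and ATF4 list lost their calls. NF-kB genes also lost theirs without WT medium replicate 3 (adjusted p = 0.057), and STAT3 targets without replicate 3 of cKO (adjusted p = 0.056) or WT medium (adjusted p = 0.12). Tolerogenic molecules did so without cKO medium replicate 1 or WT medium replicate 2 (adjusted p = 0.053 each) or 3 (adjusted p = 0.1). Neutrophil and granulocyte precursor markers rose in 11 of 15 and fell in 0 (12 and 0 adjusted over the list alone), with the granule protease Prtn3 at 2.40 ± 0.36 (adjusted p = 0.00096, and 0.67 with an estimated correlation). Their list level was 5.60, 5.88 and 4.17 in cKO medium replicates 1 to 3, against 3.31 to 4.21 in WT medium. Of 12 members of the BAG6 and tail-anchored insertion list, Bag6 included, 3 rose and 2 fell, and of 17 genes flanking Bag6 1 rose and 3 fell, with camera adjusted p of 0.89 and 0.69.

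In all, 3583 genes were called in cKO medium, 1876 higher and 1707 lower. RLE scaling gave 1738 and 1881, upper-quartile scaling 1758 and 1856 and DESeq2 1785 and 1943. With only the compared groups in the fit the count was 2306, and on the TPM scale the calls were 1434 higher and 2209 lower.

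The effect of Bag6 deletion under LPS was read from cKO and WT cells given LPS. Pim1 was again far higher in cKO cells, at 511 ± 32.6 against 18.4 ± 3.59 CPM (SD, n = 3), a 27.8-fold difference. Cebpb was 23.9-fold and Snx20 14.2-fold higher, and the inducible heat shock gene Hspa1b was 9.22-fold higher, a value that is uncertain because reads can be shared with its near-identical copy Hspa1a. Adm, the gene of the vasoactive peptide adrenomedullin, and Ddit4 were 7.49-fold and 7.29-fold higher. The largest falls were in Lrrc14 (log2 fold change -2.69 ± 0.21), the monocyte chemokines Ccl7 (-2.67 ± 0.57) and Ccl2 (-2.13 ± 0.40), Emr4 (-2.41 ± 0.61), the phosphatase regulator Ppp1r10 (-2.20 ± 0.29) and the scaffold gene Cass4 (-2.15 ± 0.43). Adjusted p for these genes ranged from 1.6e-16 for Pim1 to 0.0077 for Emr4.

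Tnf, Il6 and Il1b were higher in cKO cells under LPS. Tnf was at 210 ± 48.6 against 86.4 ± 4.53 CPM (log2 fold change 1.28 ± 0.15, adjusted p = 6.6e-06), Il6 at 194 ± 10.9 against 107 ± 15.9 (0.86 ± 0.16, adjusted p = 0.00047) and Il1b at 3440 ± 205 against 2050 ± 261 (0.75 ± 0.16, adjusted p = 0.0016). Of 28 proinflammatory cytokines and chemokines 8 rose and 3 fell (8 and 3 adjusted over the list alone), among them Il27 at 1.79 ± 0.29 and Ccl3 at 0.62 ± 0.11. The list did not pass (camera adjusted p = 0.13, and 0.92 with an estimated correlation), with a median of 0.18, and of -0.17 on the TPM scale. It passed without WT LPS replicate 1 (adjusted p = 0.046). Cd274, the gene of the inhibitory ligand PD-L1, rose by 0.96 ± 0.19 (adjusted p = 0.0012) and Tsc22d3 by 1.29 ± 0.19 (adjusted p = 8.4e-05). The stress regulator Atf4 rose by 0.48 ± 0.09 and the endoplasmic reticulum chaperone Hspa5 by 0.59 ± 0.14, while Xbp1 fell by 0.48. Acly, which makes cytosolic acetyl-CoA, fell by 0.63 and Hmgcs1, an early enzyme of cholesterol synthesis, by 0.80. Without WT LPS replicate 2 Hmgcs1 was at -0.51 (adjusted p = 0.042). Il12b, the shared subunit of IL-12 and IL-23, was at 798 ± 71.5 against 381 ± 40.5 CPM, without overlap of libraries. Its difference of 1.07 ± 0.71 did not pass in the shared fit of all 6 groups (adjusted p = 0.27). It passed with only the 2 groups compared (1.09, adjusted p = 5.1e-05). The Socs3 rise of 0.40 ± 0.15 (adjusted p = 0.04) lost its call without WT LPS replicate 1 (0.25) or 3 (0.34) or cKO LPS replicate 1 (0.40) or 3 (0.41). Without WT LPS replicate 2 it was 0.62 (adjusted p = 0.00083). The call was also lost with upper-quartile factors (0.34, adjusted p = 0.07), with only the groups compared (0.42, adjusted p = 0.055) and without the first replicate of both cKO groups (0.37, adjusted p = 0.12). On the TPM scale Socs3 (0.07, adjusted p = 0.68), Il1b (0.39, adjusted p = 0.058), Atf4 (0.13, adjusted p = 0.34) and Hspa5 (0.23, adjusted p = 0.17) lost their calls. So did the list members Stat3 (0.16, adjusted p = 0.17) and Oasl2 (0.17, adjusted p = 0.23), and Mx2 with the smaller pseudocount (0.69, adjusted p = 0.15). Il10 (-0.90 ± 0.57), Cd86 (-0.20 ± 0.41), Cd40 (0.57 ± 0.50), Havcr2 (0.45 ± 0.60), Ddit3 (0.43 ± 0.20), Cyp11a1 (0.49 ± 0.57), Arg1 (-0.24 ± 0.13) and Itgax (-0.23 ± 0.13) did not pass. With only the groups compared Cd40 (0.59, adjusted p = 0.0015) and Ddit3 (0.45, adjusted p = 0.0048) passed, both without overlap of libraries. On the TPM scale Il10 (-0.88, adjusted p = 0.0056), Arg1 (-0.59, adjusted p = 0.0013) and Itgax (-0.59, adjusted p = 0.0011) passed.

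Of 23 cytosolic chaperones, 14 rose and 2 fell under LPS (15 and 2 adjusted over the list alone; camera adjusted p = 8.7e-07, and 0.25 with an estimated correlation), among them the HSP70 cofactors Dnajb1 (1.12 ± 0.11) and Dnaja1 (1.01 ± 0.11). Of 20 glycolysis genes, 11 rose and 0 fell (13 and 0 adjusted over the list alone; adjusted p = 0.00061, and 0.68 with an estimated correlation), including the glucose transporter Slc2a1 (1.53 ± 0.12), the regulatory kinase Pfkfb3 (1.54 ± 0.16) and Pgk1 (0.58 ± 0.09). Of 18 glucocorticoid receptor targets, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with the clock gene Per1 at 1.35 ± 0.10 and the metallothionein genes Mt1 at 1.26 ± 0.13 and Mt2 at 1.77 ± 0.21 (adjusted p = 0.001, and 0.40 with an estimated correlation). Of 20 IL-10 and STAT3 targets, 7 rose and 3 fell (8 and 4 adjusted over the list alone; adjusted p = 0.0077, and 0.45 with an estimated correlation), with the NF-kB cofactor Bcl3 at 1.67 ± 0.27 and Stat3 at 0.52 ± 0.09. Of 20 NF-kB pathway genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.0096, and 0.68 with an estimated correlation), with Nfkbia at 0.80 ± 0.11. Of 33 interferon-stimulated genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.0096, and 0.92 with an estimated correlation), with Mx2 at 1.04 ± 0.21 and Oasl2 at 0.52 ± 0.13. Of 26 tolerogenic molecules, 10 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.036, and 0.68 with an estimated correlation), with the haem oxygenase gene Hmox1 at 0.77 ± 0.13. The last list lost its call without cKO LPS replicate 2 (adjusted p = 0.067).

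Granulocyte markers did not pass under LPS (0 of 15 rose or fell, camera adjusted p = 0.59), nor did cholesterol efflux genes (4 rose and 2 fell of 16, adjusted p = 0.76). The 5 sex-linked genes (1 rose, adjusted p = 0.76) and the 3 tested lymphocyte markers (0 passed, adjusted p = 0.83) did not pass either. In all, 4194 genes were called, 1901 higher and 2293 lower. RLE scaling gave 2171 and 1975, and DESeq2 2183 and 1962. Upper-quartile scaling moved the median of all genes to -0.11 and the TPM scale moved it to -0.31, where the calls were 724 higher and 5424 lower. The medians of the raised lists other than cytosolic chaperones were then below 0.

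The difference between the LPS responses of cKO and WT cells was tested as a genotype by LPS interaction. A positive (negative) value means a more positive (negative) log2 change with LPS in cKO cells. Egr1, a zinc finger factor induced early by many stimuli, had an interaction of -3.40 ± 0.25 on the log2 scale (adjusted p = 5.9e-07), Fosb, an AP-1 subunit, -3.69 ± 0.52 and Klf2, a quiescence regulator, -3.36 ± 0.53. Hdgfrp3 had -3.36 ± 0.41. The interaction was positive for Id3, an inhibitor of basic helix-loop-helix factors (2.81 ± 0.46), Gadd45g, a stress sensor (2.67 ± 0.28), Qpct, the glutaminyl cyclase (2.55 ± 0.30), and the linker histone gene Hist1h1e (3.10 ± 0.47), whose reads can be shared with other histone genes. Adjusted p for these 8 genes was 0.00077 or lower.

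Tnf had a larger rise with LPS in cKO cells (1.25 ± 0.22, adjusted p = 0.0011), as did Atf4 (0.53 ± 0.13, adjusted p = 0.0066), whose call was lost on the TPM scale (0.26, adjusted p = 0.21). Xbp1 (-0.97 ± 0.12, adjusted p = 4.7e-05) and Acly (-0.77 ± 0.19, adjusted p = 0.0083) had negative interactions. Xbp1 was at -1.03 with LPS in cKO cells and -0.05 in WT cells, and Acly at -1.11 and -0.34. The Bag6 interaction of 0.72 ± 0.25 (adjusted p = 0.048) lost its call without any one of 10 of the 12 libraries, with values from 0.60 to 0.98 over all 12. It also lost it with upper-quartile factors (0.69, adjusted p = 0.058), only the groups compared (0.77, adjusted p = 0.08), on the TPM scale (0.34, adjusted p = 0.27) and without the first replicate of both cKO groups (0.47, adjusted p = 0.29). Il6 (-0.62 ± 0.25), Il1b (-0.56 ± 0.23), Cd274 (0.57 ± 0.27), Socs3 (-0.59 ± 0.21), Il12b (0.22 ± 2.39) and Il10 (-1.66 ± 1.16) did not pass. Socs3 passed without WT LPS replicate 1 (-0.73) or WT medium replicate 1 (-0.67) or 2 (-0.68), and Il1b without WT medium replicate 1 (-0.71). Socs3 also passed with upper-quartile factors (-0.62, adjusted p = 0.042), the replicate block (-0.59, adjusted p = 0.042) and on the TPM scale (-0.85, adjusted p = 0.0027). Il6 passed with the block (-0.62, adjusted p = 0.04) and on log2(TPM + 1) (-0.82, adjusted p = 0.027) and log2(TPM + 0.1) (-0.88, adjusted p = 0.024). On the TPM scale Il1b (-0.87, adjusted p = 0.012), Il10 (-1.05, adjusted p = 0.03) and Hmgcs1 (-0.95, adjusted p = 0.015) passed. Hspa5 (0.33 ± 0.20) passed without cKO medium replicate 1 (0.55, adjusted p = 0.045) and Hmgcs1 (-0.75 ± 0.30) without WT LPS replicate 3 (-0.93, adjusted p = 0.033).

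Of 33 interferon-stimulated genes, 11 had a positive interaction and 0 a negative one (14 and 0 adjusted over the list alone; camera adjusted p = 1.1e-07, and 0.79 with an estimated correlation), among them Zbp1, a nucleic acid sensor (0.80 ± 0.14), and Trim30a (0.81 ± 0.14). Of 23 cytosolic chaperones, 10 had a positive interaction (15 positive and 1 negative adjusted over the list alone; adjusted p = 1.1e-07, and 0.23 with an estimated correlation), including Hsp90aa1 (1.14 ± 0.17) and Hsph1 (1.41 ± 0.23). Of 17 MHC class I genes 5 had a positive interaction (6 adjusted over the list alone; adjusted p = 0.0027, and 0.80 with an estimated correlation). Of 15 MHC class II genes 2 did (2 adjusted over the list alone; adjusted p = 0.045, and 0.85 with an estimated correlation). Of 33 TCA cycle and oxidative phosphorylation genes 6 had a positive interaction (7 adjusted over the list alone; adjusted p = 0.024, and 0.85 with an estimated correlation), with medians of -0.37 for LPS in WT and -0.17 in cKO cells. The interaction medians of these last 3 lists were below 0 on the TPM scale. The MHC class II list lost its call without any one of 6 of the 12 libraries, with adjusted p from 0.054 to 0.2. These were cKO LPS replicate 2, cKO medium replicate 2, WT LPS replicates 1 and 3, and WT medium replicates 1 and 2. TCA cycle genes lost theirs without cKO medium replicate 2 (adjusted p = 0.2) or WT medium replicate 3 (adjusted p = 0.21). Granulocyte markers had a negative interaction in 3 of 15 (10 adjusted over the list alone; adjusted p = 0.00031, and 0.79 with an estimated correlation), with Prtn3 at -2.56 ± 0.63. Their median was 0.53 for LPS in WT and -1.19 in cKO cells. In all, 2070 genes were called, 870 with a positive and 1200 with a negative interaction. With RLE scaling the split was 1111 positive and 901 negative, with DESeq2 1244 and 1011, on the TPM scale 419 and 2890, and without the first replicate of both cKO groups 1268 genes were called.

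The response to LPS in WT cells was measured against WT medium. Rsad2, an antiviral radical SAM enzyme, rose from 44 to 71367 counts over 3 libraries, a log2 fold change of 11.06 ± 0.71, and Ifit3 and Ifit2, which bind viral RNA, rose by 10.07 ± 0.64 and 9.59 ± 0.54. Oasl1 rose by 11.41 ± 0.51 from 12 counts in medium. Ms4a4c and Ifi44 had 3 and 2 counts in medium, and their count ratios after scaling were 2790 (95% counting interval 955 to 13500) and 1770 (490 to 14600). The largest falls were in the ribonuclease Rnase6 (-4.37 ± 0.25), the pseudouridine synthase Dkc1 (-4.28 ± 0.33), the growth regulator Myc (-4.09 ± 0.21), Fcrls (-3.75 ± 0.30), the lectin Clec10a (-3.69 ± 0.18) and B3gnt7 (-3.54 ± 0.18). Adjusted p for the 12 genes ranged from 6.5e-13 to 1e-07.

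The cytokines Il12b (0.568 ± 0.358 to 381 ± 40.5 CPM, adjusted p = 2.4e-05), Il6 (7.28 ± 1.14 to 107 ± 15.9), Il1b (377 ± 104 to 2050 ± 261) and Tnf (42.5 ± 5.02 to 86.4 ± 4.53) rose. The costimulation genes Cd40 (5.46 ± 0.66 on the log2 scale) and Cd86 (1.82 ± 0.43) rose too, as did Cd274 (2.99 ± 0.21). Il10 rose by 3.75 ± 0.72 from 5 to 55 counts (adjusted p = 0.00013). Socs3 (2.64 ± 0.16), the stress factor Ddit3 (3.24 ± 0.24), Tsc22d3 (1.94 ± 0.20), Hspa5 (0.48 ± 0.14) and Atf4 (0.38 ± 0.09) rose, the last 2 losing their calls on the TPM scale with adjusted p of 0.17 and 0.35. Itgax, which encodes CD11c, fell by 0.50 and Acly by 0.34. Acly was not called without WT LPS replicate 2 (-0.19, adjusted p = 0.20) or 3 (-0.37) or WT medium replicate 1 (-0.30) or 2 (-0.32), or with only the groups compared (-0.36, adjusted p = 0.067). Havcr2 (-1.13 ± 0.52), Xbp1 (-0.05 ± 0.09), Hmgcs1 (-0.13 ± 0.21), Cyp11a1 (0.75 ± 0.59) and Arg1 (-0.12 ± 0.13) did not pass. Havcr2 passed without WT LPS replicate 1 (-1.65, adjusted p = 0.038) or WT medium replicate 3 (-1.39, adjusted p = 0.047). It also passed with DESeq2 (-1.14, adjusted p = 0.038), only the groups compared (-1.14, adjusted p = 0.032), no count filter (-1.14, adjusted p = 1.8e-05) and the replicate block (-1.12, adjusted p = 0.0084). On log2(TPM + 1) it passed with -0.96 (adjusted p = 0.029) and on log2(TPM + 0.1) with -1.36 (adjusted p = 0.013). On the TPM scale Xbp1 (-0.30, adjusted p = 0.0045) and Arg1 (-0.37, adjusted p = 0.023) passed.

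All 33 interferon-stimulated genes rose, with a median log2 fold change of 6.19 (33 adjusted over the list alone; camera adjusted p = 5.7e-97, and 0.003 with an estimated correlation). All 17 MHC class I genes rose (17 adjusted over the list alone; adjusted p = 3.3e-15, and 0.051 with an estimated correlation), with the peptide transporter Tap1 at 2.54 ± 0.14. Of 28 proinflammatory cytokines and chemokines 24 rose and 1 fell (25 and 1 adjusted over the list alone; adjusted p = 1.3e-10, and 0.066 with an estimated correlation). Of 20 NF-kB genes 19 rose and 0 fell (19 and 0 adjusted over the list alone; adjusted p = 5e-09, and 0.051 with an estimated correlation). Of 17 maturation genes 14 rose (15 adjusted over the list alone), with Cd200, an inhibitory surface ligand, at 6.35 ± 0.30 (adjusted p = 1.9e-05, and 0.18 with an estimated correlation). Of 20 IL-10 and STAT3 targets 17 rose and 2 fell (17 and 2 adjusted over the list alone; adjusted p = 3.4e-07, and 0.034 with an estimated correlation). Of 24 p53 targets 20 rose and 3 fell (20 and 3 adjusted over the list alone; adjusted p = 9e-07, and 0.015 with an estimated correlation). Cell cycle genes fell in 26 of 28 and rose in 0 (26 and 0 adjusted over the list alone), with Ccnb2 at -2.84 ± 0.16 (adjusted p = 2.4e-14, and 0.18 with an estimated correlation). Of 19 genes of acetyl-CoA and fatty acid synthesis 15 fell and 2 rose (15 and 2 adjusted over the list alone), led by the fatty acid synthase Fasn at -3.26 ± 0.20 (adjusted p = 0.0011, and 0.039 with an estimated correlation). Of 24 cholesterol synthesis genes 17 fell and 0 rose (17 and 0 adjusted over the list alone), with the squalene epoxidase Sqle at -1.43 ± 0.12 (adjusted p = 0.00035, and 0.23 with an estimated correlation). In all, 6969 genes were called, 3537 higher and 3432 lower. The split was 2357 and 4813 on the TPM scale, and 2928 and 4073 with upper-quartile scaling.

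The response of cKO cells to LPS was measured against cKO medium. Ifit3 rose by 12.50 ± 0.77 on the log2 scale, Rsad2 by 11.78 ± 0.72, Oasl1 by 11.53 ± 0.51, and Ifit1 by 10.77 ± 0.39. The rise of the DNA-sensing family gene Ifi205 lay between the last 2. Ms4a4c went from 3 to 3449 counts, a scaled ratio of 1850 (95% counting interval 632 to 8970). The largest falls were in Cass4 (-5.06 ± 0.41), Fasn (-5.02 ± 0.29), the kinase gene Aatk (-3.98 ± 0.26), Dkc1 (-3.90 ± 0.38), the mitochondrial ATPase Atad3a (-3.76 ± 0.35) and the Rac GTPase activator Chn2 (-3.72 ± 0.29). Il6 rose by 3.26 ± 0.18, Il12b by 9.59 ± 1.16, Tnf by 2.27 ± 0.16, Il1b by 1.88 ± 0.17, Cd40 by 6.36 ± 0.70, Cd86 by 1.78 ± 0.43 and Cd274 by 3.56 ± 0.21, with adjusted p of 0.0028 or lower. Xbp1 fell by 1.03, Acly by 1.11, Hmgcs1 by 0.87 and Itgax by 0.61. The Bag6 rise of 0.76 ± 0.19 (adjusted p = 0.0018) was lost on the TPM scale (0.15, adjusted p = 0.42) and without the first replicate of both cKO groups (0.50, adjusted p = 0.071). The Il10 rise of 2.09 ± 0.76 from 8 to 22 counts (adjusted p = 0.02) was lost without cKO LPS replicate 1 (2.00) or 2 (1.53) or cKO medium replicate 2 (1.95), on the TPM scale (0.52, adjusted p = 0.058), and without the first replicate of both cKO groups (2.04, adjusted p = 0.097). Of the remaining readouts, Socs3 (2.05 ± 0.15), Ddit3 (2.99 ± 0.23), Atf4 (0.91 ± 0.09), Tsc22d3 (2.12 ± 0.20) and Hspa5 (0.81 ± 0.14) rose, the last not on the TPM scale (0.30, adjusted p = 0.057). Havcr2 (-0.54 ± 0.53), Cyp11a1 (-0.68 ± 0.51) and Arg1 (-0.15 ± 0.13) did not pass. Arg1 passed on both TPM scales (-0.68, adjusted p of 0.00017 and 0.00018), Cyp11a1 on log2(TPM + 1) (-0.94, adjusted p = 0.036) and Havcr2 on log2(TPM + 0.1) (-1.02, adjusted p = 0.043).

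All 33 interferon-stimulated genes rose in cKO cells (33 adjusted over the list alone; camera adjusted p = 1.8e-90, and 0.0042 with an estimated correlation). So did all 17 MHC class I genes (17 adjusted over the list alone; adjusted p = 2.5e-17, and 0.048 with an estimated correlation). Of 23 cytosolic chaperones 16 rose and 4 fell (16 and 4 adjusted over the list alone), with Hsph1 at 2.90 ± 0.17 (adjusted p = 0.001, and 0.25 with an estimated correlation). Of 19 fatty acid synthesis genes 14 fell and 2 rose (14 and 2 adjusted over the list alone; adjusted p = 0.00067, and 0.048 with an estimated correlation). Of 24 cholesterol synthesis genes 20 fell and 2 rose (20 and 2 adjusted over the list alone; adjusted p = 0.00072, and 0.28 with an estimated correlation). Cell cycle genes fell in 24 of 28 and rose in 1 (24 and 1 adjusted over the list alone; adjusted p = 2.3e-08, and 0.32 with an estimated correlation). In all, 7614 genes were called, 3476 higher and 4138 lower, and 1903 and 6894 on the TPM scale, where the median of all genes was -0.47. Upper-quartile scaling put that median at -0.25 here and at -0.11 in WT cells.

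**Figure D3:**
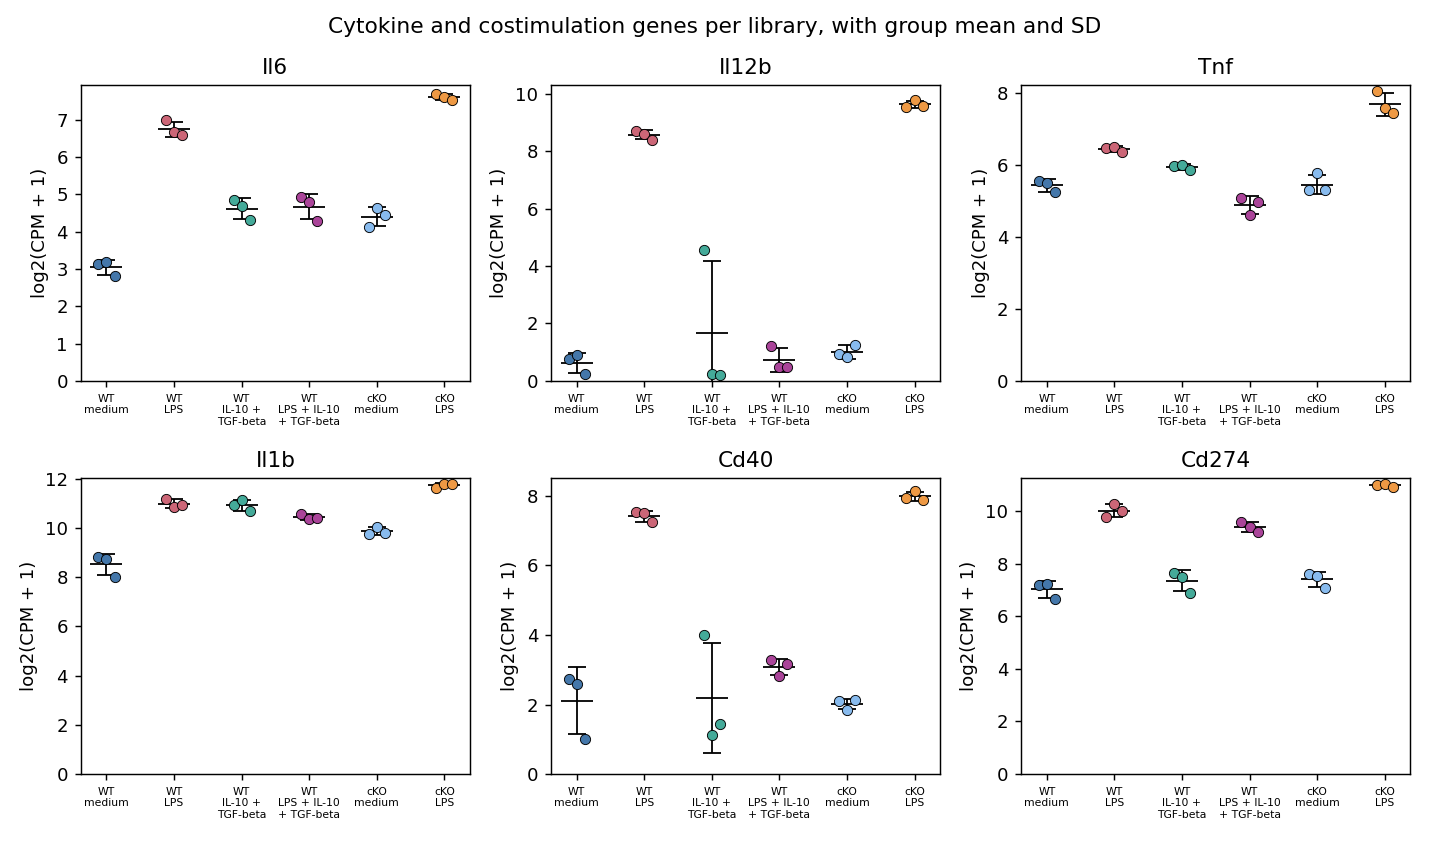
Cytokine and costimulation genes per library as log2(CPM + 1), by group. Points are libraries, and the line and bars give the mean and SD of 3 libraries. Il6 and Tnf are highest in the 3 cKO LPS libraries, and Il12b with cytokines alone is high in a single library, at 22.7 CPM.

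The effect of IL-10 and TGF-beta without LPS was read in WT cells against medium. Interferon-stimulated genes rose without added LPS: Oasl1 by 7.68 ± 0.51 on the log2 scale, Rtp4 by 6.89 ± 0.19, Rsad2 by 6.64 ± 0.64 and Oas2, which synthesises 2'-5' oligoadenylates, by 6.41 ± 0.26. Slfn4, a Schlafen family gene, rose by 7.41 ± 0.51 and Pydc3 by 6.30 ± 0.38. The lectin genes Asgr2 (-7.45 ± 0.42), Mgl2 (-4.75 ± 0.27) and Clec10a (-4.24 ± 0.19) fell, as did Tns1 (-4.68 ± 0.37), the ribonuclease Ear11 (-4.40 ± 0.57) and Lrrc32, which anchors latent TGF-beta (-4.12 ± 0.49). Adjusted p for these genes was 4.6e-05 or lower.

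Of the readouts, Il6 (1.71 ± 0.19), Il1b (2.38 ± 0.17), Socs3 (1.99 ± 0.15), Arg1, an enzyme of arginine breakdown (0.75 ± 0.14), Tsc22d3 (1.36 ± 0.20), Ddit3 (1.08 ± 0.26), Cyp11a1 (2.21 ± 0.52) and Havcr2 (1.83 ± 0.42) rose with adjusted p of 0.0031 or lower. Acly fell by 0.87 and Itgax by 1.20. Smaller rises of Tnf (0.52 ± 0.16, adjusted p = 0.014), Hspa5 (0.49 ± 0.14, adjusted p = 0.011) and Atf4 (0.27 ± 0.09, adjusted p = 0.022) lost their calls without single libraries. This held for Tnf without WT medium replicate 3 (0.42), Hspa5 without cytokine replicate 3 (0.42) or medium replicate 2 (0.39), and Atf4 without replicate 1 or 2 of either group (0.24 to 0.27). On the TPM scale these 3 had adjusted p of 0.073, 0.055 and 0.37. Atf4 also lost its call with upper-quartile factors (0.20, adjusted p = 0.084). Ddit3 lost its call with only the compared groups in the fit (1.06, adjusted p = 0.051). Il12b had 3.67 ± 1.44 (adjusted p = 0.066) and rested on cytokine replicate 1, at 22.7 CPM against 0.169 and 0.164 in the other 2 libraries. Leaving out either of these gave 4.27 with adjusted p of 0.019 and 0.017. Il10 (1.10 ± 0.93), Cd86 (0.19 ± 0.42), Cd40 (0.55 ± 0.75), Cd274 (0.34 ± 0.20), Xbp1 (0.08 ± 0.09) and Hmgcs1 (0.19 ± 0.21) did not pass, except that Cd274 passed without cytokine replicate 3 (0.53, adjusted p = 0.032).

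Of 33 interferon-stimulated genes 30 rose and 0 fell (32 and 0 adjusted over the list alone), with a median of 3.44 (camera adjusted p = 3e-87, and 0.0042 with an estimated correlation). Of 27 TGF-beta and SMAD targets 12 rose and 5 fell (14 and 6 adjusted over the list alone; adjusted p = 0.0016, and 0.24 with an estimated correlation), including Rgs1 (3.13 ± 0.17), Id1 (2.68 ± 0.18) and Pmepa1, a feedback inhibitor of TGF-beta signalling (2.56 ± 0.20). Of 18 glucocorticoid receptor targets 11 rose and 3 fell (12 and 4 adjusted over the list alone; adjusted p = 0.00013, and 0.12 with an estimated correlation), with the transglutaminase Tgm2 at 2.43 ± 0.15 and Sgk1 at 2.53 ± 0.17. Of 12 steroid synthesis genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), led by Hsd11b1, which regenerates active glucocorticoid, at 2.25 ± 0.17 (adjusted p = 0.0051, and 0.12 with an estimated correlation). MHC class II genes fell in 10 of 15 and rose in 3 (10 and 3 adjusted over the list alone), with the invariant chain Cd74 at -2.60 ± 0.25 (adjusted p = 0.00079, and 0.35 with an estimated correlation). Conventional dendritic cell markers fell in 10 of 16 and rose in 2 (11 and 3 adjusted over the list alone), with the transcription factor Zbtb46 at -3.28 ± 0.27 (adjusted p = 1.8e-07, and 0.12 with an estimated correlation).

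Macrophage markers rose in 9 of 18 and fell in 4 (9 and 4 adjusted over the list alone), with Mertk, a receptor for apoptotic cells, at 1.73 ± 0.15 and the lipoprotein Apoe at 5.52 ± 0.36 (adjusted p = 0.021, and 0.25 with an estimated correlation). The call was lost without cytokine replicate 1 (adjusted p = 0.056). Granulocyte precursor markers rose in 14 of 15 (14 adjusted over the list alone; adjusted p = 5.4e-06, and 0.25 with an estimated correlation), with Prtn3 at 3.49 ± 0.35. All 8 tested mast cell and basophil markers rose (8 adjusted over the list alone), with the mast cell protease Cpa3 at 3.95 ± 0.54 (adjusted p = 0.0007, and 0.22 with an estimated correlation). PERK and ATF4 stress genes rose in 13 of 31 and fell in 2 (13 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.053, and 0.27 with an estimated correlation). With the replicate number as a block its camera adjusted p was 0.035. In all, 4175 genes were called, 2170 higher and 2005 lower. The split was 1526 and 2946 on the TPM scale, and 1817 and 2497 with upper-quartile scaling.

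The effect of the cytokines on LPS-treated WT cells was read from LPS with IL-10 and TGF-beta against LPS alone. Il12b fell from 381 ± 40.5 to 0.710 ± 0.549 CPM, a log2 fold change of -9.01 ± 1.19 (adjusted p = 5.8e-05). Aldh1a2, which makes retinoic acid (-8.58 ± 1.17), the T cell chemokines Ccl22 (-8.42 ± 1.48) and Ccl17 (-7.22 ± 0.77), and Fscn1, an actin bundler of mature dendritic cells (-6.31 ± 0.84), also fell, as did BC035044 (-6.01 ± 0.41). Apoe was 48.6-fold higher, Angptl4, a lipoprotein lipase inhibitor, 43.1-fold, Cited1 38.0-fold, the secreted phosphoprotein Spp1 20.8-fold, the ectonucleotidase Entpd3 19.2-fold and the phosphodiesterase Pde1c 18.7-fold. Adjusted p for these genes was 0.00057 or lower.

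Il6 (-2.10), Tnf (-1.57), Cd40 (-4.49), Cd86 (-2.57), Acly (-0.86) and Itgax (-1.22) fell on the log2 scale, with adjusted p of 0.00047 or lower. Il10 fell from 55 to 4 counts (-3.89 ± 0.75, adjusted p = 0.00028). Havcr2 rose by 3.25 ± 0.48, Arg1 by 1.19 ± 0.14 and Atf4 by 0.57 ± 0.09. Smaller falls lost their calls without single libraries. These were Il1b (-0.56 ± 0.16) without WT LPS replicate 1 (-0.45), Cd274 (-0.62 ± 0.19) without WT LPS replicate 2 (-0.49) or replicate 3 of LPS with cytokines (-0.53), and Hspa5 (-0.48 ± 0.14) without WT LPS replicate 2 (-0.37) or replicate 2 of LPS with cytokines (-0.42). Socs3 (0.25 ± 0.15), Ddit3 (-0.21 ± 0.20), Xbp1 (0.04 ± 0.09), Hmgcs1 (-0.29 ± 0.21), Cyp11a1 (0.74 ± 0.53) and Tsc22d3 (0.39 ± 0.19) did not pass. Socs3 passed without WT LPS replicate 2 (0.48, adjusted p = 0.006) and Hmgcs1 without replicate 3 of LPS with cytokines (-0.57, adjusted p = 0.027). Tsc22d3 passed with only the groups compared (0.39, adjusted p = 0.029).

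Of 17 maturation genes 15 fell and 1 rose (15 and 1 adjusted over the list alone), with Marcksl1 at -2.06 ± 0.16 and the interleukin Il15 at -4.84 ± 0.50 (camera adjusted p = 2.1e-08, and 0.16 with an estimated correlation). Of 33 interferon-stimulated genes 29 fell and 1 rose (29 and 1 adjusted over the list alone), with Isg15 at -1.75 ± 0.16 and Mx1 at -2.42 ± 0.24 (adjusted p = 8.9e-10, and 0.33 with an estimated correlation). Of 28 proinflammatory cytokines and chemokines 20 fell and 1 rose (20 and 1 adjusted over the list alone; adjusted p = 1.1e-07, and 0.24 with an estimated correlation). MHC class II genes fell in 12 of 15 and rose in 1 (13 and 2 adjusted over the list alone), with their transactivator Ciita at -3.23 ± 0.32 and Cd74 at -2.67 ± 0.25 (adjusted p = 1.4e-05, and 0.33 with an estimated correlation). Of 35 ATF6 and XBP1 targets of the endoplasmic reticulum 18 fell and 2 rose (18 and 2 adjusted over the list alone), with Creld2 at -1.23 ± 0.14 (adjusted p = 0.045, and 0.56 with an estimated correlation). This list lost its call without WT LPS replicate 2 (adjusted p = 0.11) or replicate 2 or 3 of LPS with cytokines (adjusted p of 0.067 and 0.053). Cytosolic chaperones fell in 15 of 23 and rose in 2 (15 and 2 adjusted over the list alone), with Dnajb4 at -1.62 ± 0.13 (adjusted p = 0.00018, and 0.24 with an estimated correlation). Of 27 TGF-beta and SMAD targets 12 rose and 7 fell (12 and 8 adjusted over the list alone), with Tgfbi, an extracellular matrix protein, at 2.62 ± 0.16 (adjusted p = 0.0082, and 0.35 with an estimated correlation).

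Conventional dendritic cell markers fell in 10 of 16 and rose in 1 (11 and 2 adjusted over the list alone), with Zbtb46 at -3.84 ± 0.29 and Batf3 at -3.49 ± 0.29 (adjusted p = 7.4e-07, and 0.16 with an estimated correlation). Macrophage markers rose in 10 of 18 and fell in 4 (11 and 4 adjusted over the list alone), with the lipid regulator Pparg at 2.81 ± 0.17 and the growth factor receptor Csf1r at 1.41 ± 0.10 (adjusted p = 0.00061, and 0.16 with an estimated correlation). Granulocyte precursor markers rose in 9 of 15 and fell in 1 (11 and 1 adjusted over the list alone), with Prtn3 at 2.70 ± 0.37 (adjusted p = 0.015, and 0.56 with an estimated correlation). In all, 4783 genes were called, 2273 higher and 2510 lower. Upper-quartile scaling gave 2478 and 2334.

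The response to LPS in the presence of the cytokines was read against cytokines alone. U90926 rose by 7.07 ± 0.50 on the log2 scale, the acute phase genes Saa1 and Saa3 by 6.85 ± 0.29 and 4.29 ± 0.29, the glutamate transporter Slc1a2 by 4.03 ± 0.30, the interleukin-36 gene Il1f6 by 3.43 ± 0.30 and Ddit4 by 3.41 ± 0.15. The endothelin gene Edn1 (-4.28), Ccl7 (-3.75), the CTP synthase Ctps (-3.47) and Myc (-3.38) fell, as did the histone genes Hist2h3b (-3.52 ± 0.33) and Hist2h3c2 (-3.34 ± 0.37), which can share reads. Adjusted p for these genes was 3.5e-05 or lower. Cd274 (2.03 ± 0.20), Socs3 (0.90 ± 0.15), Ddit3 (1.96 ± 0.22), Atf4 (0.67 ± 0.09) and Tsc22d3 (0.97 ± 0.19) rose, and Tnf fell by 1.07, Hspa5 by 0.49 and Itgax by 0.51.

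Il6 (0.06 ± 0.18), Il10 (-1.24 ± 0.98), Cd86 (-0.93 ± 0.44), Cd40 (0.41 ± 0.70), Havcr2 (0.29 ± 0.38), Xbp1 (-0.09 ± 0.09), Cyp11a1 (-0.73 ± 0.46) and Arg1 (0.32 ± 0.13) did not pass. Cd86 passed with only the groups compared (-0.93, adjusted p = 0.042), the replicate block (-0.98, adjusted p = 0.049) and no count filter (-0.93, adjusted p = 7.6e-12). Cyp11a1 passed with only the groups compared (-0.73, adjusted p = 0.028), as did Arg1 (0.32, adjusted p = 0.031), which also passed with DESeq2 (0.31, adjusted p = 0.046). Xbp1 passed on the TPM scale (-0.23, adjusted p = 0.033). Il12b had -3.31 ± 1.41 (adjusted p = 0.072), and without cytokine replicate 1 it was 2.05 (adjusted p = 0.031). Without cytokine replicate 2 or 3 it was -3.92, with adjusted p of 0.019 and 0.02. Without replicate 1 Cd40 passed as well (2.37, adjusted p = 0.0011), and without cytokine replicate 2 Arg1 passed (0.45, adjusted p = 0.013). The falls of Il1b (-0.49 ± 0.16), Acly (-0.33 ± 0.13) and Hmgcs1 (-0.61 ± 0.21) each lost the call without single libraries. This held for Il1b without cytokine replicate 2 (-0.37) or replicates 2 (-0.45) or 3 (-0.48) of LPS with cytokines. It held for Acly without replicate 1 or 2 of either group (-0.30 to -0.29), and for Hmgcs1 without cytokine replicate 3 (-0.48) or replicate 1 or 2 of LPS with cytokines (-0.49 each). Hmgcs1 also lost it with only the groups compared (adjusted p = 0.085). All 28 cell cycle genes fell (28 adjusted over the list alone), with Cdk1 at -2.32 ± 0.14 and Mcm6 at -2.68 ± 0.16 (camera adjusted p = 1.2e-34, and 0.079 with an estimated correlation). All 33 interferon-stimulated genes rose (33 adjusted over the list alone), with a median of 1.34 (adjusted p = 3.7e-17, and 0.23 with an estimated correlation). Of 20 NF-kB genes 14 rose and 0 fell (14 and 0 adjusted over the list alone), with Sod2 at 1.36 ± 0.12 (adjusted p = 5.1e-07, and 0.22 with an estimated correlation). Of 20 glycolysis genes 15 rose and 0 fell (16 and 0 adjusted over the list alone), with Pfkfb3 at 2.93 ± 0.17 and Hk2 at 1.13 ± 0.10 (adjusted p = 1.2e-05, and 0.37 with an estimated correlation). Of 24 p53 targets 15 rose and 2 fell (16 and 2 adjusted over the list alone; adjusted p = 1.6e-06, and 0.025 with an estimated correlation). In all, 5575 genes were called, 2836 higher and 2739 lower. The split was 1950 and 3499 on the TPM scale, 2717 and 2851 with upper-quartile scaling, 2780 and 2782 with RLE scaling and 2785 and 2807 with DESeq2.

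The change in the LPS response with cytokines was tested as a cytokine by LPS interaction in WT cells. A negative value means a more negative log2 change with LPS when the cytokines were present. It can also reflect a rise with cytokines alone, as for Il1b and Socs3. Il12b had an interaction of -12.67 ± 1.79 on the log2 scale (adjusted p = 0.00026), Oasl1 -9.98 ± 0.59 and Rsad2 -9.47 ± 0.79. Without cytokine replicate 1 the Il12b interaction was -7.31 (adjusted p = 0.0016). The leukaemia inhibitory factor receptor Lifr (3.39 ± 0.29), Angptl4 (3.09 ± 0.32), the kinase gene Matk (2.75 ± 0.40) and the lectin Klrb1b (2.72 ± 0.39) had positive interactions. All 33 interferon-stimulated genes had a negative interaction (33 adjusted over the list alone), with a median of -4.75 (camera adjusted p = 3.4e-168, and 0.00011 with an estimated correlation). Much of this was their rise with cytokines alone (median 3.44), as cytokines added to LPS gave a median of -0.98. Of 28 proinflammatory cytokines and chemokines 24 had a negative interaction and 0 a positive one (25 and 0 adjusted over the list alone), with Ccl4 at -2.94 ± 0.18 and Il6 at -3.81 ± 0.26 (adjusted p = 4.6e-25, and 0.015 with an estimated correlation).

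Tnf (-2.09 ± 0.22), Il1b (-2.93 ± 0.23), Cd40 (-5.05 ± 0.96), Cd86 (-2.76 ± 0.61), Socs3 (-1.74 ± 0.21), Hspa5 (-0.97 ± 0.20), Ddit3 (-1.28 ± 0.33) and Il10 (-5.00 ± 1.25, from at most 55 counts per group) also had negative interactions, with adjusted p of 0.0087 or lower. Tnf and Hspa5 rose with LPS alone and fell with LPS in the presence of the cytokines. Without cytokine replicate 1 the Cd40 interaction was -3.09 (adjusted p = 0.0056). Cd274 (-0.96 ± 0.28) lost its call without replicate 1 of the cytokine group (-0.80), replicate 2 of LPS (-0.83) or replicate 3 of LPS with cytokines (-0.87), and Tsc22d3 (-0.97 ± 0.28) without replicate 2 of the cytokine group (-0.81) or replicate 3 of LPS (-0.88). Havcr2 (1.42 ± 0.65), Arg1 (0.45 ± 0.19), Atf4 (0.29 ± 0.13) and Hmgcs1 (-0.48 ± 0.29) did not pass. Havcr2 passed with the replicate block (1.42, adjusted p = 0.019) and without replicate 3 of LPS with cytokines (1.73, adjusted p = 0.048), which also gave Hmgcs1 a call (-0.76, adjusted p = 0.045). Arg1 passed without cytokine replicate 2 (0.59, adjusted p = 0.034) and Atf4 without WT LPS replicate 1 (0.40, adjusted p = 0.021). With upper-quartile factors Arg1 (0.55, adjusted p = 0.047) and Atf4 (0.39, adjusted p = 0.028) passed, and on the TPM scale Arg1 (0.56, adjusted p = 0.039). Of 17 MHC class I genes 16 had a negative interaction (16 adjusted over the list alone), with the transactivator Nlrc5 at -2.20 ± 0.24 (adjusted p = 3.7e-13, and 0.095 with an estimated correlation). Of 17 maturation genes 9 had a negative interaction (10 adjusted over the list alone; adjusted p = 4.7e-05, and 0.21 with an estimated correlation). Of 31 proteasome genes 10 had a negative interaction (14 adjusted over the list alone; adjusted p = 0.0052, and 0.55 with an estimated correlation). Glycolysis genes had a positive interaction in 12 of 20 and a negative one in 2 (12 and 2 adjusted over the list alone), with Aldoc at 1.71 ± 0.17 (adjusted p = 0.0011, and 0.45 with an estimated correlation). In all, 2487 genes were called, 1055 with a positive and 1432 with a negative interaction. Upper-quartile scaling gave 1466 and 1166, and the TPM scale 1465 and 1145.

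**Figure D4:**
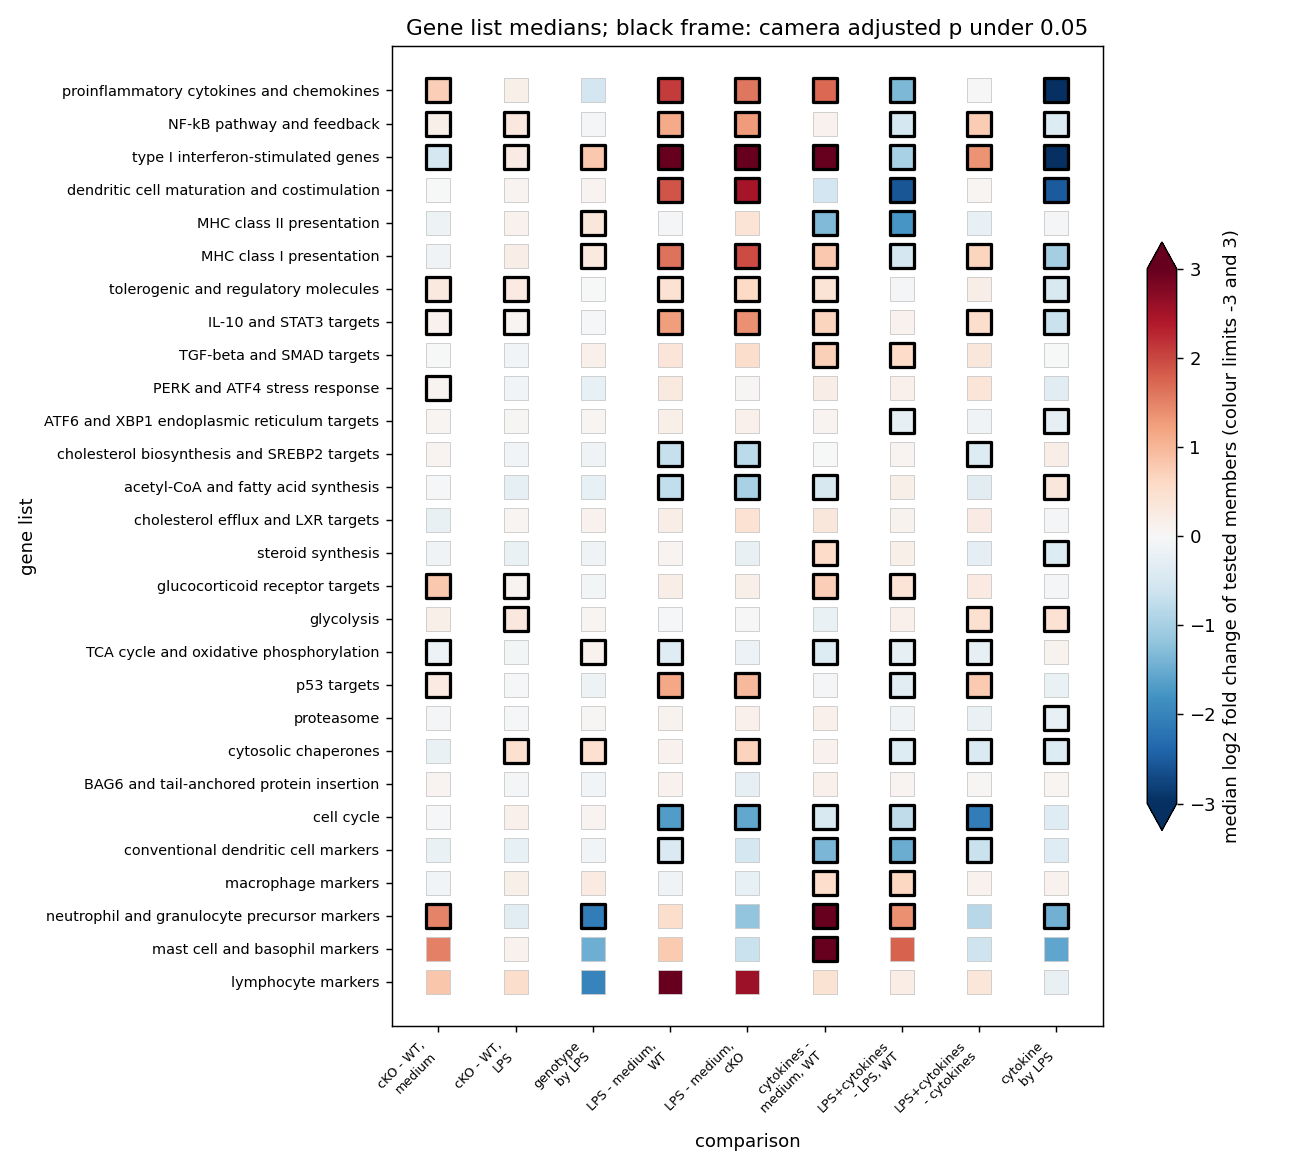
Median log2 fold change of the tested members of 28 gene lists (vertical axis) in the 9 comparisons (horizontal axis), as a colour scale from -3 to 3, with values beyond the limits shown in the end colours. Black frames mark lists with a camera adjusted p under 0.05. Interferon-stimulated genes reach medians of 6.19 and 7.11 with LPS, 3.44 with cytokines alone and -4.75 in the cytokine by LPS interaction.

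Whether cKO and WT cells differed in the genes that the tolerising cytokines changed was asked by comparing fold changes across all 11876 genes. These genes are not independent replicates. The difference between cKO and WT cells is called deletion here. Deletion in medium and in LPS correlated with r = 0.379 ± 0.046 (jackknife SE, Spearman rho 0.377), against a simulated r of -0.0018 ± 0.034 with no effect. In both, 774 genes were higher where independent lists would share 300, and 654 lower against 330. Without the count filter r was 0.111. Genes higher in one and lower in the other numbered 108 and 80 against 362 and 273. Deletion under LPS and cytokines added to LPS, which share the WT LPS libraries, correlated with r = 0.0366 ± 0.041 (rho -0.0297). This r was 0.308 without the count filter and -0.0101 with at least 5 CPM. It was 0.0893, 0.116 and 0.142 without WT LPS replicates 1, 2 and 3. The shared controls alone gave a simulated r of 0.48 ± 0.028. The covariance was 0.0277 against a simulated 0.055, a difference of -0.0277, and part of any overlap may come from the shared controls, since 3 control libraries cannot be divided into parts of at least 2.

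Without shared libraries, deletion in medium against cytokines added to LPS gave r = 0.11 ± 0.064 (rho 0.071), and deletion under LPS against cytokines in medium gave 0.0753 ± 0.043 (rho 0.0883). In the first of these 549 genes were higher in both against 359 and 420 lower in both against 361. There 335 were higher with deletion and lower with cytokines against 396, and 339 the other way against 327. In the second 519 were higher in both against 347 and 416 lower in both against 387. There 333 were higher with deletion and lower with cytokines against 321, and 324 the other way against 419.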

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

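The tests of library size, of LPS in the cytokine cultures and of genes near Bag6 without Pim1 and H2-T10 or within 1 Mb were chosen only after the results were seen.

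By an interaction test the LPS response differed between cKO and WT cells in 2070 genes. The interaction was 1.25 on the log2 scale for Tnf (edgeR adjusted p = 0.0011), 0.53 for Atf4, -0.97 for Xbp1, -0.77 for Acly and 0.72 for Bag6. The Bag6 call was lost without any one of 10 of the 12 libraries and in other settings named in the results. List medians were 0.81 for interferon-stimulated genes, 0.49 for cytosolic chaperones, 0.34 for MHC class II and 0.29 for MHC class I genes. They were 0.14 for TCA cycle genes and -2.10 for granulocyte markers. With an estimated correlation 0 of these lists passed. MHC class II genes lost the call without any one of 6 libraries and TCA cycle genes without any one of 2, as named in the results. Of 60 splits of the 12 libraries, 2 called as many genes, the real one included. The median of the other splits was 0 genes. Splits that mix the genotypes within both treatments put genotype effects into the spread, whatever the interaction. This share therefore cannot exclude chance. The highest other split called 2698. It exchanged all 3 LPS libraries and 1 medium library between the genotypes, which by construction adds the genotype effects of both treatments, a structure of the samples.

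With the cytokines the LPS response of WT cells differed in 2487 genes. The interaction was -12.67 for Il12b, -5.05 for Cd40, -5.00 for Il10, -3.81 for Il6, -2.93 for Il1b and -2.76 for Cd86. It was -2.09 for Tnf, -1.74 for Socs3, -1.28 for Ddit3, -0.97 for Hspa5, -0.97 for Tsc22d3 and -0.96 for Cd274. Without cytokine replicate 1 it was -7.31 for Il12b and -3.09 for Cd40. List medians were -4.75 for interferon-stimulated genes, -3.05 for cytokines and chemokines, -2.52 for maturation genes and -1.44 for granulocyte markers. They were -1.03 for MHC class I genes, -0.67 for STAT3 targets, -0.48 for tolerogenic molecules, -0.41 for NF-kB genes, -0.40 for steroid synthesis and -0.40 for cytosolic chaperones. They were -0.28 for ATF6 and XBP1 targets, -0.25 for the proteasome, 0.33 for fatty acid synthesis and 0.46 for glycolysis. With an estimated correlation 2 of these 14 lists passed, interferon-stimulated genes and cytokines and chemokines. Steroid synthesis genes lost the call without any one of 6 libraries (adjusted p from 0.058 to 0.1). These were WT LPS replicate 3, replicates 2 and 3 of LPS with cytokines, cytokine replicates 1 and 3, and WT medium replicate 2. Granulocyte markers lost it without replicate 3 of any of the 4 groups (adjusted p from 0.079 to 0.12). Of 60 splits 1, the real one, called as many (highest other 2443). Mixing puts cytokine effects into the spread, so chance stays open.

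Each comparison of a pair of groups has 10 splits, too few for a share under 0.05. The highest other split called 3 genes for cKO against WT in medium (real 3583) and 32 for cytokines against medium (real 4175). It called 0 for cKO against WT under LPS (real 4194), LPS in WT (real 6969) and LPS in cKO cells (real 7614). It also called 0 for cytokines added to LPS (real 4783) and LPS added to cytokines (real 5575). In each, 1 split called as many genes, the real one.

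Pim1 and H2-T10 (2.63 in medium and 2.43 under LPS on the log2 scale, chosen after its values were seen) were strongly raised in cKO cells, and both lie on chromosome 17 with Bag6. Within 10 Mb of Bag6, 7 of 262 genes, these 2 among them, changed at least 2-fold in 1 direction in both cKO comparisons, against 214 of 11574 elsewhere (odds ratio 1.46), and without these 2 genes 5 of 260 did (odds ratio 1.04, 95% interval 0.332 to 2.5, Fisher's exact two-sided p = 0.82). Within 1 Mb 4 of 84 did, and without H2-T10 3 of 83, and the odds ratio of 2 for alleles of another strain within 1 Mb (95% interval 0.401 to 6.14, Fisher's exact two-sided p = 0.2) leaves open that such alleles, carried along with the targeted allele, may contribute. The other 4 tested H2-T genes together lost 194 ± 123 CPM (SE) under LPS, or 143% ± 90.8 of the H2-T10 gain of 136 CPM. H2-T9 fell from 476 to 254 CPM, H2-T23 from 373 to 268 and H2-T24 from 107 to 74.1, while H2-T22 rose from 184 to 351. The sum takes these genes alike, whether or not they share reads with H2-T10. Reads assigned to the wrong copy may contribute to the H2-T10 rise, which the sum cannot settle. An effect of Bag6 loss stays open for both genes.

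Granulocyte markers were raised in cKO medium and with the cytokines alone, and mast cell markers with the cytokines and in 4 of 8 genes in cKO medium (camera adjusted p = 0.096, and 0.02 without cKO medium replicate 3 and 0.04 without WT medium replicate 1), with the abundant S100a8 at 312 ± 98.3 CPM (SD) in WT medium, 878 ± 404 in cKO medium and 2800 ± 646 with the cytokines, and Cpa3 at 0.367 ± 0.298, 1.38 ± 0.827 and 5.85 ± 3.01. A difference in library size was argued against, since the group with raised markers had the deeper libraries in 1 of the 2 comparisons. Within groups both list levels varied together over the 18 libraries (r = 0.77 ± 0.078 bootstrap SE, rho = 0.68, permutation p = 0.00082 for r, and r = 0.765 without the 2 farthest libraries). Admixture of other bone marrow cells may therefore contribute, although cells were sorted for high CD11c, and all 15 granulocyte markers in the files and 8 of 10 mast cell markers had enough counts to be tested. Effects of genotype and cytokines on the sorted cells stay open.

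Interferon-stimulated genes were raised by the cytokines without LPS. LPS at the level of the LPS cultures was argued against, since 46.9% of tested genes differed between cytokines with and without LPS. A smaller amount of LPS and an effect of the cytokines cannot be told apart here. The mean change of 20 NF-kB genes was -0.04 ± 0.18 (SE over members), within its error of 0, against 0.75 when LPS was added to the cytokines.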

How the results depend on the processing

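The alternatives without Rn45s and without the first replicate of both cKO groups were chosen only after the results were seen. Of 365 named pairs of gene and comparison 283 were called. Of 6380 alternative values 6183 kept direction and side of the threshold, 99 lost the call, 97 gained one (24 of them without a count filter) and 1 reversed. A call was lost by 16 pairs when 1 library was left out and by 21 under another planned setting. The reversal was Il12b for LPS added to cytokines, with 2.05 without WT cytokine replicate 1 and -4.18 to 2.05 over the libraries left out. That library held 22.7 CPM of Il12b, as given above. Low counts limit recovery, as the simulated genes missed at 4-fold show.

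A 2-fold requirement, stricter by construction, left 884, 988 and 732 genes for cKO against WT in medium, under LPS and their interaction. It left 2961 and 3852 for LPS in WT and cKO cells, 1548 for cytokines, 1704 for cytokines added to LPS, 1693 for LPS added to cytokines and 1127 for their interaction. With only the groups compared, cKO against WT in medium gave 2306 genes. The genotype interaction gave 3309 and 3403 on log2(TPM + 1) and log2(TPM + 0.1), and 1268 without the first cKO replicates. The cause was not tested.

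Camera with an estimated correlation called 0 lists for both cKO comparisons, the genotype interaction and cytokines added to LPS. It called 4 and 5 for LPS in WT and cKO cells, 1 each for cytokines and LPS added to cytokines, and 2 for the cytokine interaction. Fry, which does not compare a list with other genes, called 24, 26 and 22 for LPS in WT, in cKO cells and added to cytokines. Single libraries left out gave 5 (without cKO medium replicate 2) to 12 lists for cKO against WT in medium. Without WT medium replicate 3 that comparison gained the MHC class I, MHC class II and dendritic cell lists (adjusted p = 0.0026 each), and cytokines against medium the maturation (adjusted p = 0.014) and proteasome lists (adjusted p = 0.042).

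The correlation of cKO against WT under LPS with cytokines added to LPS was 0.0782 with DESeq2, 0.308 without a count filter and -0.0101 with at least 5 CPM. It ranged from 0.0219 to 0.142 without single libraries. That of both cKO comparisons was 0.111 without a filter, 0.457 with at least 5 CPM, 0.442 on log2(TPM + 1), and 0.33 to 0.399 without single libraries. Bag6 for LPS in cKO cells was 0.15 and 0.19 on the 2 TPM scales and 0.50 without the first cKO replicates, where its call was lost (adjusted p = 0.071), as on both TPM scales. Its genotype interaction was 0.69 with upper-quartile factors, 0.77 with only the groups compared, 0.34 and 0.41 on the TPM scales, 0.47 without the first cKO replicates, and 0.60 to 0.98 without single libraries. The cause was not tested.

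With the replicate block cytokines against medium, where the numbers pair, gave 4276 genes, and besides the PERK and ATF4 list it changed no call of a named gene or list. In other 2-group comparisons pairing was not shown, but both cKO replicates 1 look female. The block gave 3666, 4257 and 2141 genes for cKO against WT in medium, under LPS and their interaction, 7035 and 7623 for LPS in WT and cKO cells, 4882 for cytokines added to LPS, 5690 for LPS added to cytokines and 2560 for the cytokine interaction. In 0 of those pairs did every library correlate best with its number. The cytokine interaction also holds WT medium and LPS with cytokines, whose numbers pair (r of 0.25, 0.11 and 0.21). There the block gave Havcr2 a call.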

Other observations

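Immediate early genes, which respond within minutes to many stimuli, were examined as a list chosen only after the results were seen. Of 16 tested, 12 rose and 0 fell in cKO medium against WT medium, with a median log2 fold change of 1.48. Under LPS 4 rose and 6 fell in cKO cells, with a median of -0.24. In the genotype by LPS interaction 1 was positive and 13 were negative, with a median of -1.48.

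Maturation genes differed between libraries of the same group. In WT cells with cytokines alone, replicate 1 held 85.3 CPM of Ccr7, a chemokine receptor that guides dendritic cells to lymph nodes, against 7.19 and 2.06 in replicates 2 and 3. It held 292 CPM of the chemokine Ccl22 against 5.84 and 6.58. In WT medium, replicate 3 held 17.2 CPM of Ccr7 against 212 and 216 in replicates 1 and 2, and 187 CPM of Ccl22 against 827 and 761.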
